A study of Homo sapiens with 4 samples.

How the data were processed

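Per the sample labels, RNA was extracted with TRIzol and libraries were made with an MGIEasy mRNA kit. The series has 4 libraries, 1 for each of 4 groups: H1975 sensitive and H1975 resistant to osimertinib, and HCC827 sensitive and HCC827 resistant to gefitinib. Groups were taken from the drug response label of each sample. Separate cultures are not described, and no group has a replicate.

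Per the submitters' processing notes, HISAT2, Bowtie2 and RSEM were used with the hg19 build; their versions and settings are not given in the sources used here. The deposited files give, per NCBI Gene ID, RSEM expected counts, which are estimated read counts that need not be whole, and FPKM values, which the authors scaled by transcript length and library total. The expected counts are not normalized. In H1975 55.1% and 55.2% of the listed genes had whole expected counts, and in HCC827 69.5% and 69.8%. Values that are not whole arise where RSEM shares reads between genes, so named genes with non-whole counts and a known near-identical copy were marked as uncertain; other genes with non-whole counts are not marked one by one. Whether strand was used in counting is not given in the sources used here, and reads of overlapping antisense genes cannot be told apart. The files list only genes above 0, with a lowest FPKM of 0.01. The H1975 files name versioned RefSeq transcripts including predicted models for 65.8% and 66.1% of genes, and the HCC827 files name unversioned transcripts with no predicted models. Annotation and depth therefore differ between the lines but not within a pair: all 15446 genes listed in both H1975 files and all 14328 listed in both HCC827 files had identical transcript lists.

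Depth was 22145163 and 22217897 expected counts in H1975 and 10934558 and 11034837 in HCC827, so counting intervals are wider in HCC827 for a gene at the same level. Gene IDs were matched to symbols in a RefSeq gene table of the GRCh38.p14 assembly, used for names and neighbour order alone because the build differs. A symbol was found for 98.6% of genes in the H1975 files and 99.8% in the HCC827 files; genes without one held 0.121%, 0.107%, 0.062% and 0.065% of the counts and stayed in all totals.

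Expected counts were rounded to whole numbers. Within each pair, libraries were scaled by TMM factors from edgeR (1.005 and 0.995 in H1975, 0.981 and 1.019 in HCC827). Genes with at least 1 FPKM and 20 counts in at least 1 library of the pair were considered. The log2 ratio of resistant to sensitive normalised counts used no prior count. Its 95% interval was the exact Clopper-Pearson interval of the conditional binomial, which covers counting error only, since each group has 1 library. Reads were not counted as unique molecules, so the interval may be too narrow even for that error. A library at 0 was set to a floor of 3 counts per library, or to the count that corresponds to 0.01 FPKM where that is larger, and such ratios are bounds written as "at least". The second part of that floor was set after the files were seen to list no value below 0.01 FPKM. Calls needed a ratio of at least 2-fold and an interval that excluded 0. No test or p-value was used within a line.

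A set of 33 gene lists was fixed before the data were examined, covering receptor tyrosine kinases and EGFR ligands, MAPK output and immediate early genes, epithelial and mesenchymal identity, integrins, TGF-beta, YAP/TAZ, Wnt and Notch signalling, cell cycle, CDK inhibitors, BCL2 family, NRF2 targets, drug metabolism, interferon, antigen presentation, cytokines, lung, squamous, neuroendocrine and stem cell markers, metabolism, housekeeping genes, cancer-testis antigens and other cell types. COL3A1 stands in both the mesenchymal and the fibroblast list. Unmatched list members include LGR5, SFTPA1, SCGB1A1, SCGB3A2, CHGB, PAGE5, CD3E, MS4A1 and the mitochondrially encoded genes, whose Gene IDs no file listed. NDUFA4 was also unmatched, because its symbol has changed to COXFA4; all 4 files list it, and it was left out of the oxidative phosphorylation list. For each list the median log2 ratio was placed among 10000 random lists of the same size, matched on 10 expression classes; this percentile describes these libraries and is no test. Overlap between the lines was set beside the product of the list sizes over the genes considered in both and beside 1000 gene shuffles within expression classes.

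The test over both lines used edgeR's quasi-likelihood test on the rounded expected counts of genes listed in all 4 files, with the cell line as a block, TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05, two-sided. The pairing comes from the design, since each resistant library has the sensitive library of its own line as partner. Genes absent from a file, such as MAL2, were not in this test; an alternative that admits them was added after the data were seen. With 2 lines as replicates, p-values rest only on the spread between these libraries. The quasi-likelihood test drew each gene's variance partly from other genes, with 3.77 prior degrees of freedom. A gene whose ratios differ between the lines can therefore still have a low p-value.

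The rule for named genes was fixed in advance. For each line it took the 8 genes called higher and the 8 called lower whose interval bound nearest to 0 was largest in size, EGFR, ERBB2, ERBB3, MET and AXL whatever their values, and at most 4 called members of each list by ratio, or its 2 most expressed members where none was called. For both lines together it took 8 genes per shared direction and up to 5 per opposite direction, and the 3 lowest p-values of the test where none passed. Genes named outside this rule are list members counted in the test over both lines, or are said to have been chosen after their values were seen. Some genes that the rule selects are not reported.

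Alternatives were DESeq2 size factors, totals alone, no filter, a filter of 5 FPKM, ratios of FPKM with a pseudocount of 1 or 0.1, thresholds of 1.5-fold and 4-fold, intervals wholly beyond 2-fold, and for the test over both lines DESeq2, limma, no block, no filter and, without the block, each library left out in turn. The calling step was tested on simulated data: of 100 genes changed by 1.5 on the log2 scale, 99 were called among 11872 genes in H1975 and 98 among 11890 in HCC827, while 6 and 15 unchanged genes were called. The intervals covered the true value for 95.1% and 95.6% of genes. This simulation drew counting error alone, so it checks the calculation and not how often differences between cultures are called. For the test over both lines, run on 13036 genes with a simulated biological coefficient of variation of 0.1, 89% of 2-fold and 100% of 8-fold changes were recovered, with 9 false calls. Changes in that simulation had the same size in both lines, so it does not cover changes that differ between them. Every simulated gene had the same coefficient of variation, so it does not cover variances that differ between genes either. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The libraries, not the conditions, are what the ratios within a line compare.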

Results

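Messenger RNA was profiled in 2 human lung adenocarcinoma cell lines, H1975 and HCC827, each as a line sensitive to an inhibitor of the EGFR tyrosine kinase and as a line resistant to it. Both are established lines that carry activating mutations of EGFR, the receptor tyrosine kinase targeted by these drugs. The H1975 cells were sensitive or resistant to osimertinib, an irreversible EGFR inhibitor, and the HCC827 cells were sensitive or resistant to gefitinib, a reversible EGFR inhibitor. Each of the 4 groups had 1 library. The libraries held 22145163 expected counts (sensitive) and 22217897 (resistant) in H1975, and 10934558 (sensitive) and 11034837 (resistant) in HCC827. The files listed 16356, 15934, 14986 and 15159 genes, with the libraries in the same order. Pearson correlations of log2(FPKM + 1) were taken across the 17490 genes listed in at least 1 file. A gene absent from a file was given no expression there. These correlations were 0.972 between the H1975 libraries and 0.956 between the HCC827 libraries. The correlation was 0.8999 between the sensitive libraries of the 2 lines and 0.9025 between their resistant libraries; genes are not independent replicates.

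Because each group had 1 library, no difference within a line has a replicate check, and no p-value is given for it. Whether the cells were in drug at harvest, and how the resistant lines were derived, is not given in the sources used here. Ratios compare the resistant with the sensitive library of the same line. Bracketed ranges are 95% exact intervals that cover counting error only. A gene was called higher or lower where it differed by at least 2-fold and its interval excluded 0 on the log2 scale.

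The comparison within H1975 asked which transcripts distinguished osimertinib-resistant from sensitive cells. Genes of epithelial identity were far lower in the resistant library: ESRP1, an epithelial splicing regulator, had 3815 counts in the sensitive and 1 in the resistant library (log2 ratio −11.89 [−17.19, −9.41]). GRHL2, a transcription factor of epithelial cells, had 1466 and 2 counts (−9.51 [−12.56, −7.65]). The membrane protein MAL2 and the basement membrane protein LAD1 had 3544 and 3158 counts in the sensitive library and were not listed in the resistant one, which made them at least 1174-fold and 1047-fold lower. The genes furthest higher in the resistant library included WNT5A, a secreted Wnt ligand (33.1-fold), INHBA, which encodes a subunit of activins (19.9-fold), and the homeobox gene MEOX1 (18.2-fold). Of 11872 genes considered, 381 were called higher and 1016 lower, and 97 and 457 of these differed by at least 4-fold.

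Among the remaining genes at the low end of the H1975 comparison, ST14 and SPINT1 belong to the fixed epithelial list, and TMEM30B and AP1M2 do not. TMEM30B had a log2 ratio of −10.42 [−15.72, −7.94], AP1M2, a subunit of an epithelial clathrin adaptor, was at least 523-fold lower, and the membrane-bound protease ST14 and its inhibitor SPINT1 were 234-fold and 411-fold lower. At the high end, TMPRSS15, the gene of enteropeptidase, had 9 counts in the sensitive and 817 in the resistant library (6.51 [5.58, 7.65]). LYPD6 (33.7-fold), the interleukin receptor subunit IL2RB (33.0-fold), CRACD (33.4-fold) and TRIML2 (20.2-fold) completed that end.

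EGFR itself had 35.6 FPKM in the sensitive and 24.6 FPKM in the resistant H1975 library, a log2 ratio of −0.53 [−0.59, −0.46] that was under 2-fold. ERBB2 (−0.78), MET (−0.26) and AXL (16.9 and 33.1 FPKM, just under 2-fold) were likewise not called. ERBB3, the kinase-impaired partner receptor, was 47.1-fold lower. Among the EGFR family and its ligands, 4 of 8 measured members were lower and 1 was higher: AREG was 23.1-fold, TGFA 5.98-fold and EREG 2.93-fold lower, while NRG1, a ligand of ERBB3, was 2.18-fold higher. The list's median log2 ratio was −1.16, at percentile 0.03 among random lists matched on expression. Of 14 other receptor tyrosine kinases and ligands, MERTK (10.5-fold) and DDR1 (3.35-fold) were lower and ROS1 (2.07-fold) was higher. MAPK pathway output was low as a list (median −0.46, percentile 0.09), with DUSP5, DUSP4 and SPRY4, feedback inhibitors of the pathway, lower by 3.88-fold, 2.76-fold and 2.30-fold, and the other 11 of 14 members not called. None of the 8 measured immediate early genes was called in H1975; MYC had a log2 ratio of 0.74 and JUNB of −0.15.

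Of 24 epithelial genes, 22 were lower in the resistant H1975 library and none was higher (median −6.33, percentile 0; −2.90 on the log2(FPKM + 1) scale). The mesenchymal list did not move as a whole (median −0.11, percentile 20.2), with 4 of 18 members higher and 4 lower. Its higher members included WNT5A and ZEB2, a repressor of epithelial genes (6.37-fold higher), and its lower members included the cadherin CDH11 (at least 29.8-fold) and the collagen gene COL1A2 (8.87-fold). VIM, the mesenchymal intermediate filament, had 545 FPKM in the sensitive and 2051 FPKM in the resistant library (log2 ratio 1.92 [1.90, 1.94]). Integrins and basement membrane genes were lower in 9 of 16 cases and higher in none (median −1.67, percentile 0). ITGB6 was 130-fold, LAMA3 28.6-fold, ITGB4 24.4-fold and COL17A1 18.8-fold lower, the latter 3 being components of epithelial attachment to the basement membrane. Markers of other cell types were sparse: of the blood cell list, 2 members were measured and CSF1R was 3.51-fold lower, and of the fibroblast and endothelial list only CDH5 was measured (9.35-fold lower).

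Signalling targets gave mixed results in H1975. TGF-beta signalling and targets had 3 of 16 members higher and 2 lower, with INHBA and BAMBI (4.96-fold) higher and PMEPA1 (3.21-fold) and LTBP2 (3.06-fold) lower. Of 23 YAP/TAZ targets, CCN2 (2.21-fold) and RBMS3 (2.09-fold) were higher and ANKRD1 (4.07-fold) and IGFBP3 (3.36-fold) lower. In Wnt and Notch signalling, 6 of 13 members were lower, led by the receptor NOTCH3 (242-fold) with JAG2 (12.1-fold) and WNT7B (9.94-fold), and 2 were higher, among them AXIN2 (3.82-fold). NF-kappaB and cytokine genes had 8 of 19 members higher and 2 lower (median 0.83, percentile 100). TNF (7.12-fold) and the chemokine CCL2 (4.45-fold) were higher, whereas IL1B (181 and 3 counts, −5.91 [−8.20, −4.34]) and IL1A (20.3-fold) were lower.

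The interferon response list had a median log2 ratio of 0.59 in H1975, at percentile 100, although 18 of its 22 members were not called. MX2 (2.84-fold), OAS2 (2.55-fold) and IFIT1 (2.14-fold) were higher, and IFI27 was lower (log2 ratio −1.59). Within antigen presentation, the 4 called members of 17 all belong to the MHC class II pathway and were lower: HLA-DRA had 232 counts in the sensitive library and none in the resistant one, at least 76.9-fold lower, HLA-DPA1 had a log2 ratio of −7.08 [−12.39, −4.58], the invariant chain CD74 was 17.7-fold and the class II transactivator CIITA 4.68-fold lower. HLA-DPA1 counts were not whole, so that reads shared with related genes make its value uncertain.

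Proliferation genes differed little in H1975: none of 29 cell cycle genes was called, with log2 ratios of 0.06 for MCM7 and 0.42 for PCNA. Of 14 CDK inhibitors and p53 targets, GDF15 (22.8-fold), CDKN1C (4.64-fold) and CDKN1A (4.18-fold) were lower and CDKN2C was 3.01-fold higher. In the BCL2 family, the antiapoptotic gene BCL2 had 14 and 189 counts (log2 ratio 3.76 [2.98, 4.66]), BIK was 2.25-fold lower and the other 11 of 13 measured members were not called. NRF2 targets had 6 of 17 members lower, among them HMOX1 (4.71-fold), AKR1C1 (10.3-fold), AKR1C3 (6.87-fold) and AKR1B10 (3.09-fold). These AKR1 genes have non-whole counts and close copies in the genome, and are uncertain. Drug transport and metabolism had 4 of 10 members lower (median −0.85, percentile 0.06): CYP24A1 (20.7-fold), the efflux pump gene ABCG2 (3.61-fold), ALDH1A3 (3.50-fold) and CYP1A1 (2.80-fold).

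Lineage lists were low or sparsely measured in H1975. FOXA2 (17.0-fold) and MUC1 (5.45-fold) were lower among 4 measured lung lineage genes. Of 6 squamous and basal genes 4 were lower, namely IVL (91 counts and 1, −6.50 [−11.82, −3.98]), S100A2 (17.9-fold), TP63 (974 and 121 counts) and SPRR1B (at least 9.94-fold). SYT1 (2.84-fold) and UCHL1 (2.25-fold) were lower among 3 measured neuroendocrine genes. Among 6 stem cell markers, ITGA6 was 3.60-fold lower and BMI1 2.55-fold higher. Of 2 measured cancer-testis antigens, MAGEB2 was 11.6-fold higher. Metabolic and housekeeping lists were nearly flat. No member was called among 18 glycolysis genes (GAPDH −0.03, ENO1 0.21), 17 cholesterol synthesis genes (FDPS −0.36), 24 cytosolic ribosomal protein genes (RPS2 −0.31, RPS18 0.44) or 18 oxidative phosphorylation genes (ATP5F1B 0.05, COX4I1 −0.32). The cholesterol synthesis median of −0.36 nevertheless lay at percentile 0.07. The only called members were ANGPTL4 among 11 hypoxia genes (3.49-fold lower), CPT1A among 13 fatty acid metabolism genes (2.17-fold lower) and PHGDH among 17 ATF4 and unfolded protein response genes (2.16-fold lower). No mitochondrially encoded gene was listed in any file.

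**Figure D1:**
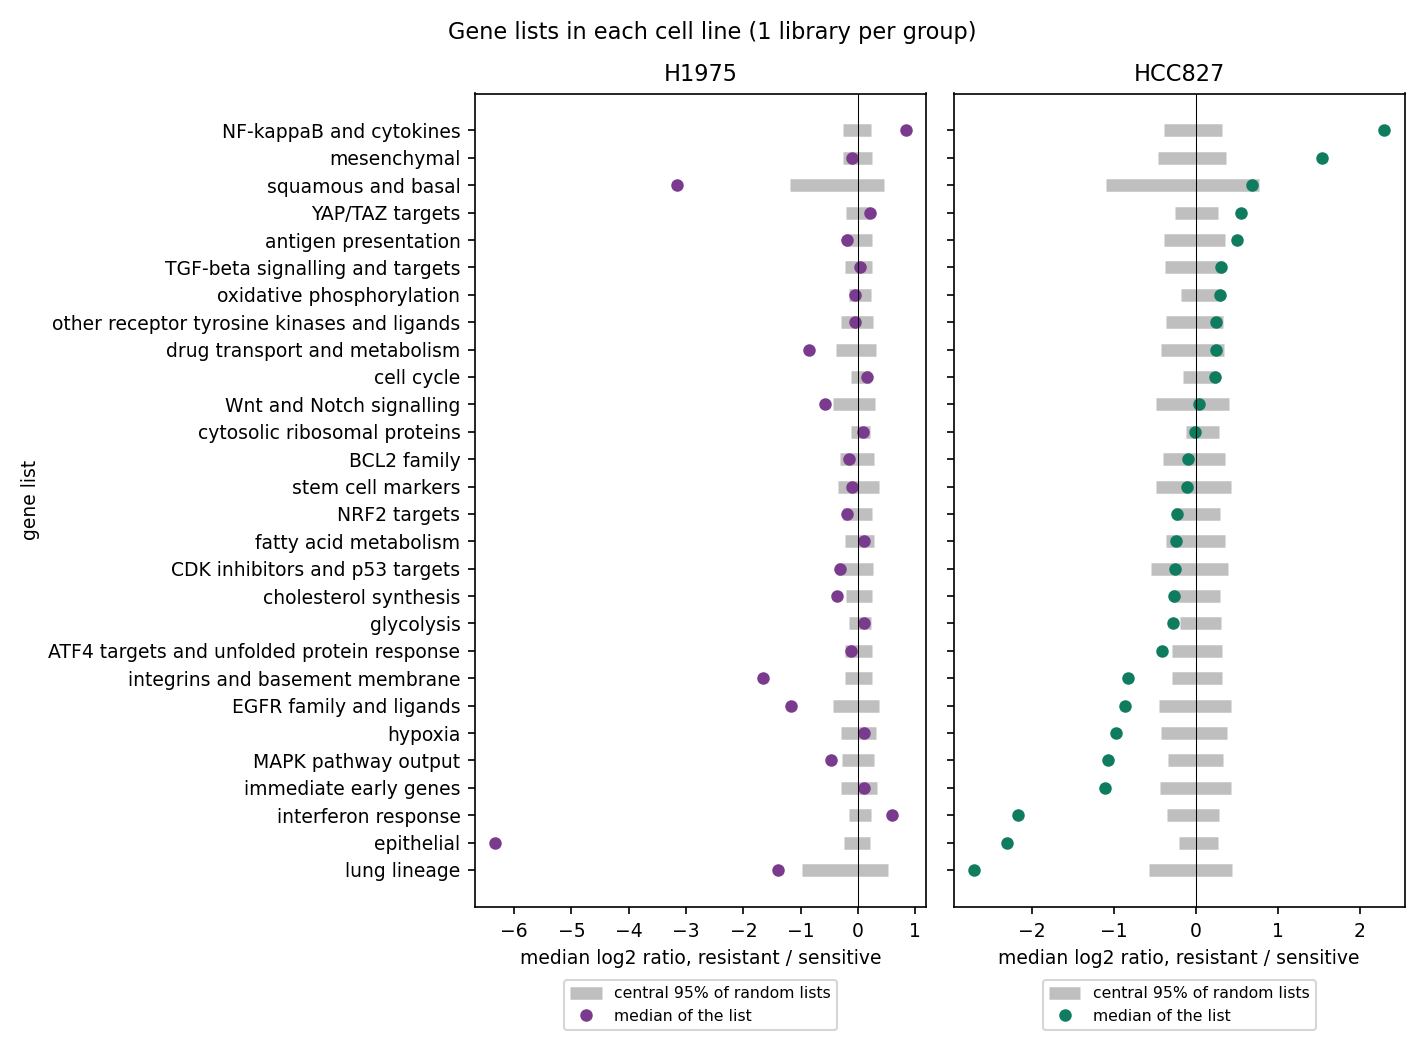
Median log2 ratio (resistant over sensitive library, x axis) of each fixed gene list with at least 3 measured members in both lines (y axis), for H1975 on the left and HCC827 on the right. Points are list medians and grey bars the central 95% of 10000 random lists matched on expression, and the panels differ in scale; the epithelial median lay at −6.33 in H1975 and −2.31 in HCC827 (−2.90 and −2.16 on the log2(FPKM + 1) scale), and the interferon median at 0.59 and −2.17.

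The comparison within HCC827 asked which transcripts distinguished gefitinib-resistant from sensitive cells. Epithelial and lung lineage genes were lower in the resistant library: GRHL2 had 901 and 3 counts (log2 ratio −8.30 [−10.58, −6.75]), RAB25, a GTPase of epithelial vesicle recycling, had 641 and 1 (−9.39 [−14.70, −6.91]), and NKX2-1, the lung lineage transcription factor, had 630 and 2 (−8.37 [−11.42, −6.51]). CDKN2A, which encodes inhibitors of the cell cycle, had 295 FPKM in the sensitive and 0.40 FPKM in the resistant library (−9.62 [−11.25, −8.40]). The proinflammatory gene IL32 (86.1-fold), the acute phase gene CRP (303-fold), SERPINB2, which encodes a plasminogen activator inhibitor (at least 202-fold), and the collagen gene COL12A1 (142-fold) were higher. Of 11890 genes considered, 838 were called higher and 1302 lower, and 309 and 458 of these differed by at least 4-fold.

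Other genes at the low end of HCC827 were PRODH, which encodes proline dehydrogenase (3375 and 2 counts, −10.79 [−13.84, −8.94]), the surfactant-associated gene SFTA2 (826 and 1, −9.76 [−15.06, −7.28]), AGR2, a secretory pathway protein of epithelia (677 and 1, −9.47 [−14.78, −6.99]), ADGRF1 (at least 531-fold lower) and the adhesion molecule CEACAM6 (at least 434-fold lower). At the high end stood the adhesion molecule CADM1 with 1 and 294 counts (8.13 [5.64, 13.44]), TENM3 (at least 136-fold), TMEM52B (83.8-fold) and SERPINB4 (75.6-fold). SERPINB4, CEACAM6, ADGRF1 and TMEM52B had non-whole counts in HCC827 and are uncertain, SERPINB4 and CEACAM6 having close copies in the genome.

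EGFR expression in HCC827 was 850 FPKM in the sensitive and 568 FPKM in the resistant library (log2 ratio −0.64 [−0.66, −0.62]), both above the 35.6 FPKM of sensitive H1975. ERBB2 (−0.88) and MET (0.25; 205 and 257 FPKM) were not called, and ERBB3 was 3.28-fold lower. AXL, a receptor kinase of the TAM family, had 4.74 and 64.5 FPKM and was 14.1-fold higher. Of 9 EGFR family members and ligands, AREG was 4.19-fold lower, HBEGF 5.24-fold and NRG1 3.64-fold higher, and the median was −0.87 (percentile 0.09). Other receptor tyrosine kinases and ligands had 6 of 15 members higher, among them FGFR1 (4.75-fold) and TYRO3 (3.52-fold), and 2 lower, MERTK (6.90-fold) and DDR1. MAPK pathway output was lower in 8 of 14 members and higher in none (median −1.08, percentile 0), with DUSP6 16.4-fold, DUSP5 4.50-fold, SPRY4 2.79-fold and PHLDA1 2.33-fold lower. Immediate early genes followed, with 5 of 9 members lower, EGR1 by 9.72-fold, FOS by 9.39-fold and KLF4 by 4.16-fold, and KLF6 2.98-fold higher.

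**Figure D2:**
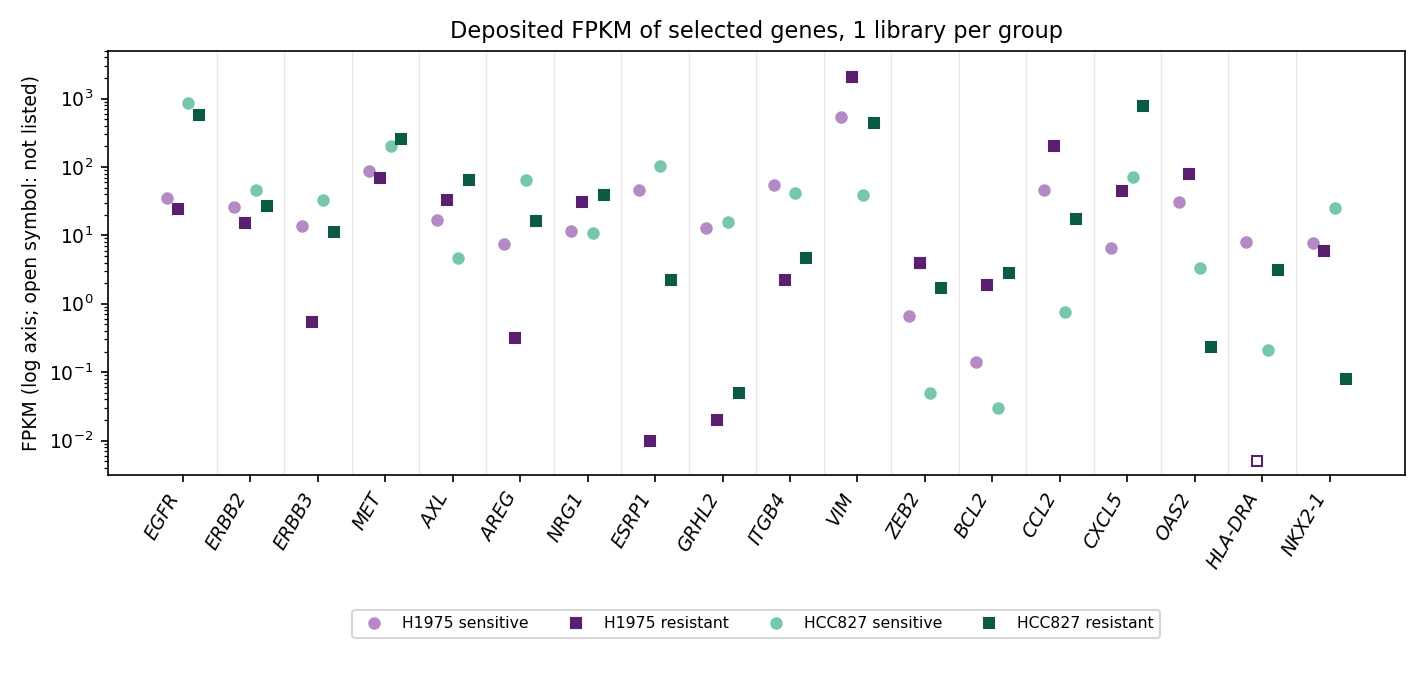
Deposited FPKM (y axis, log scale) of 18 genes (x axis) in the 4 libraries; circles are sensitive, squares resistant, and an open symbol at the axis floor marks a gene that the library's file did not list. EGFR stood at 850 and 568 FPKM in HCC827 and at 35.6 and 24.6 FPKM in H1975, whereas ESRP1 was lower in the resistant library of each line.

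Of 24 epithelial genes, 22 were lower in resistant HCC827 cells and none higher (median −2.31, percentile 0, and −2.16 on the log2(FPKM + 1) scale); besides GRHL2 and RAB25, ESRP1 was 48.2-fold lower and OVOL1 had 270 and 3 counts (−6.56 [−8.85, −5.00]). The mesenchymal list was high (median 1.54, percentile 100), with 6 of 12 members higher: ZEB2 (32.8-fold), SNAI2 (13.6-fold), VIM (10.7-fold) and TAGLN (9.70-fold) led, and NT5E was lower. Integrins and basement membrane genes had 9 of 19 members lower and 3 higher (median −0.83, percentile 0). COL17A1 (27.1-fold), ITGB6 (21.8-fold) and ITGB4 (9.42-fold) were lower, whereas THBS1, which encodes thrombospondin (26.3-fold), and ITGB3 (9.88-fold) were higher. Lung lineage genes were lower in 5 of 8 cases and higher in 1 (median −2.71, percentile 0), with the protease NAPSA 150-fold, the mucin MUC5B 18.8-fold and MUC1 7.65-fold lower. Markers of other cell types were again sparse: LYZ was the only measured blood cell marker (log2 ratio −0.17), and LUM, a fibroblast proteoglycan, had 3 and 66 counts (4.39 [2.78, 6.71]).

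Cytokine genes were higher in HCC827: 14 of 18 NF-kappaB and cytokine genes were called higher and none lower (median 2.30, percentile 100). CCL2 was 22.3-fold higher, PTGS2, which encodes an inducible cyclooxygenase, had 57 and 1316 counts, CXCL1 was 21.3-fold higher and CCL20 had a log2 ratio of 3.32 [1.29, 6.46]. CXCL1 shares sequence with related chemokine genes and is uncertain. Interferon response genes went the other way, with 19 of 20 members lower and none higher (median −2.17, percentile 0). MX1 was 29.0-fold, OAS2 16.3-fold, IFI44 13.5-fold and OASL 11.8-fold lower. Antigen presentation had 5 of 17 members higher, all of the class II pathway, from levels close to 0: HLA-DRA had 3 and 45 counts (3.84 [2.20, 6.17]), CD74 was 7.42-fold and HLA-DPA1 at least 7.63-fold higher, and HLA-DRB1 had a log2 ratio of 5.95 [3.42, 11.28]. CD274, which encodes PD-L1, was the only lower member (−1.11). HLA-DRB1 is one of several near-identical genes and is uncertain.

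TGF-beta signalling and targets had 4 of 16 members higher in HCC827, INHBA (at least 24.5-fold) and TGFB2 (3.57-fold) among them, while ID1 was 2.56-fold lower. YAP/TAZ targets had 8 of 23 members higher and 3 lower (median 0.55, percentile 99.99), with ANKRD1 46.1-fold and RBMS3 4.25-fold higher and NT5E 6.55-fold lower. Wnt and Notch signalling was split, with 3 of 10 members higher, including DKK1 (3.74-fold) and TCF7 (3.14-fold), and 3 lower, including NOTCH3 (8.97-fold) and HES1 (3.21-fold).

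Of 29 cell cycle genes, CCNE1 (2.34-fold) and CDC6 (2.04-fold) were higher and none was lower. CDKN2A and its neighbour CDKN2B (log2 ratio −7.43 [−12.75, −4.94]) were lower among 15 CDK inhibitors and p53 targets, as was TP53INP1 (3.69-fold), and CDKN1C was 2.31-fold higher. BCL2 had 2 and 107 counts (log2 ratio 5.67 [3.78, 8.74]) and BID, a proapoptotic member of the family, was 9.01-fold higher; the other 11 of 13 measured BCL2 family genes were not called. NRF2 targets had 3 of 19 members higher and 4 lower: the glutathione peroxidase gene GPX2 was 37.3-fold lower, and the uncertain near-copies AKR1C1 and AKR1C2 were 18.7-fold and at least 45.5-fold higher. Drug transport and metabolism had 4 of 14 members higher and 3 lower. The efflux pump gene ABCB1 was 4.16-fold and ALDH1A1 3.32-fold higher, CYP24A1 was 6.01-fold lower, and UGT1A6 (6.49 [3.97, 11.80]) shares exons with other members of its locus and is uncertain.

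Hypoxia genes were lower in 5 of 10 cases (median −0.98, percentile 0.02), with EGLN3 15.9-fold, NDRG1 5.18-fold, VEGFA 2.49-fold and PDK1 2.28-fold lower. Glycolysis had 3 of 18 members lower, PGK1 (3.86-fold), HK2 (2.68-fold) and PFKL (2.04-fold). ATF4 targets and unfolded protein response genes were lower in 6 of 17 cases and higher in none, led by DDIT4 (11.8-fold), CHAC1 (4.88-fold), PHGDH (3.67-fold) and ASNS (3.02-fold). Fatty acid metabolism had FABP5, a fatty acid binding protein, with 221 and 3 counts (−6.27 [−8.56, −4.71]) and FASN, the fatty acid synthase, with 60.1 and 1.87 FPKM (33.4-fold lower). SREBF1, which regulates lipid synthesis, was 2.87-fold lower and ACSL1 7.55-fold higher among its 13 measured members. Of 18 cholesterol synthesis genes 3 were lower, STARD4 (3.15-fold) and FDFT1 (2.06-fold) among them. RPS6 (2.67-fold lower) was the only called member of 24 cytosolic ribosomal protein genes, and none of 18 oxidative phosphorylation genes was called (ATP5F1B 0.54, COX4I1 0.08). Squamous and basal genes had 4 of 8 members higher and 3 lower; TRIM29 (log2 ratio 5.36 [3.46, 8.43]) and SPRR3 (4.02 [2.06, 7.12]) were higher and TP63 was 27.8-fold lower, while KRT16 (23.7-fold lower) is uncertain because of related keratin genes. SYT1 was 4.50-fold lower among 2 measured neuroendocrine genes. Stem cell markers were split, with CD44 2.41-fold higher and SOX2 5.76-fold lower. Of 4 cancer-testis antigens, MAGEC2 (38.1-fold) and SSX1 (at least 16.5-fold) were higher and PRAME 2.23-fold lower.

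The lines were then set side by side. Genes called lower in both resistant libraries included ESRP1, GRHL2 and OVOL1 of the epithelial list, the mucin MUC16 (63.9-fold in H1975 and 140-fold in HCC827), PROM2 (50.5-fold and 112-fold; non-whole counts), and the secreted protease KLK6 (log2 ratios −9.08 [−14.38, −6.59] and −8.05 [−10.33, −6.50]). S100A14 (−7.24 [−10.30, −5.38] and −6.57 [−7.89, −5.52]) and the prostaglandin transporter gene SLCO2A1 (−8.59 [−13.90, −6.10] and −5.64 [−6.78, −4.71]) were also lower in both. Genes called higher in both included BCL2 (log2 ratios 3.76 [2.98, 4.66] and 5.67 [3.78, 8.74]), ZEB2 (6.37-fold and 32.8-fold), IL32 (6.10-fold and 86.1-fold) and the neutrophil chemokine CXCL5 (6.98-fold and 10.2-fold), which has a close copy and non-whole counts and is uncertain. CRACD (33.4-fold and 14.3-fold, from at most 6 counts in the sensitive libraries), PLAC8 (11.2-fold and 7.67-fold), TMEM52B (8.47-fold and 83.8-fold) and INHBA (19.9-fold and at least 24.5-fold) were also higher in both.

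Among the 10961 genes considered in both lines, 382 were lower in both, where independent lists would share 74.97 and gene shuffles within expression deciles shared 113 on average and 139 at most. Likewise, 108 genes were higher in both, against 14.4 for independent lists and a highest shuffle of 33. The opposite pattern was rarer: 20 genes were higher in H1975 and lower in HCC827 (24.2 for independent lists, shuffle mean 35.1), and 65 were lower in H1975 and higher in HCC827 (44.7 for independent lists, shuffle mean 65.7). The log2 ratios of the 2 lines had a Pearson correlation of 0.424 and a Spearman correlation of 0.307 across genes.

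**Figure D3:**
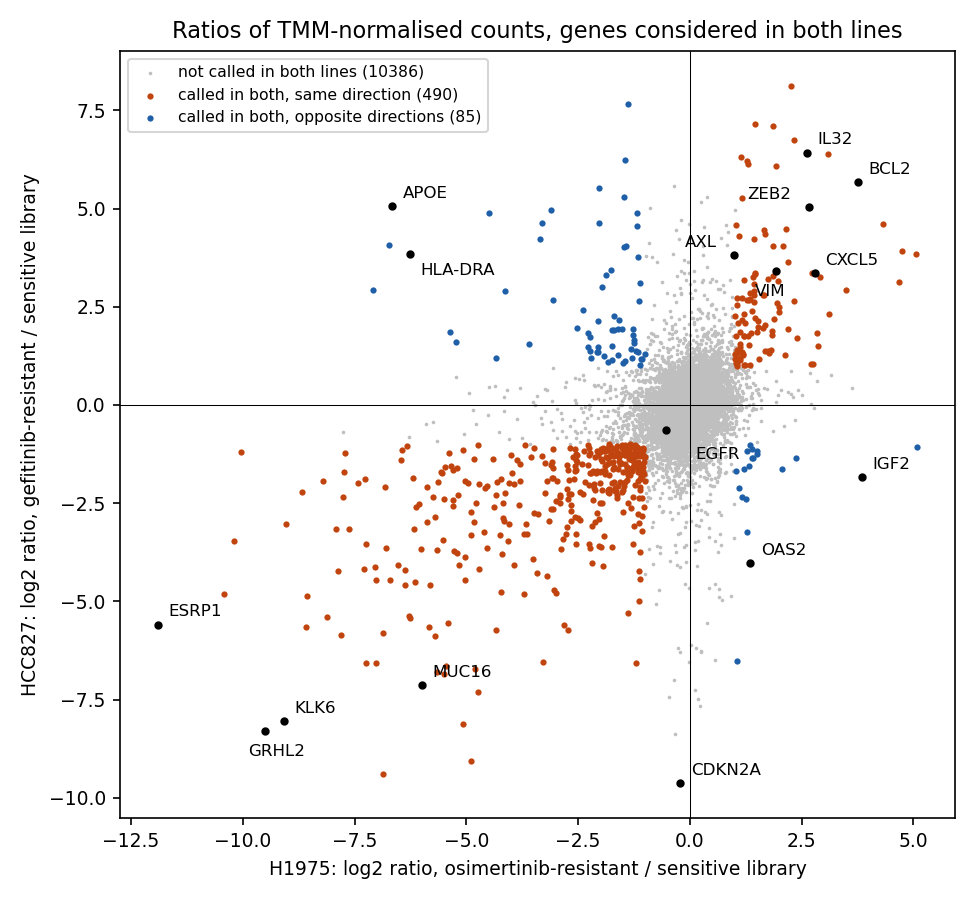
Log2 ratio of TMM-normalised counts, resistant over sensitive library, in H1975 (x axis) and HCC827 (y axis) for the 10961 genes considered in both lines. Orange points are the 490 genes called in the same direction in both lines and blue points the 85 called in opposite directions, and labelled genes are black; most of the orange points lie at the lower left, where GRHL2, ESRP1 and KLK6 stand.

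A test over both lines, with the lines as replicates and the cell line as a block, asked for changes common to both pairs. GRHL2 had a fitted log2 fold change of −8.79, KLK6 of −8.31 and MUC16 of −6.71, with the lowest p-values of the test. GRHL2 and KLK6 had at most 3 counts in either resistant library, so the size of their fold changes is poorly determined. GRHL2, KLK6 and MUC16 each had an adjusted p of 0.056 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each was lower in both of 2 lines. No gene of 13036 tested therefore passed 0.05, while 1352 had an unadjusted p under 0.05. The count was 443 (111 higher, 332 lower) with DESeq2's Wald test and 8 (all lower) with limma on log2(FPKM + 1).

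Over the fixed lists, no member passed over all genes tested by edgeR, and counts below are adjusted over the list alone. There was no adjustment for the number of lists, and 1352 of all 13036 tested genes had an unadjusted p under 0.05. Passing does not mean that the lines had ratios of like size. ERBB3 passed with log2 ratios of −5.56 in H1975 and −1.71 in HCC827. Of 23 epithelial genes tested, 21 passed, all lower, and 7 of 19 integrin and basement membrane genes passed, all lower, COL17A1, ITGB4 and ITGB6 among them. For NF-kappaB and cytokines 9 of 19 passed, all higher, including SOD2, TNF, IL6, CXCL8 and CCL2. TNF had 1 and 6 counts in HCC827, below the filter there, so its pass says little about that line. The EGFR family and ligands had 6 of 10 passing: TGFA, AREG, EREG, ERBB2 and ERBB3 were lower and NRG1 higher. ZEB1, VIM and ZEB2 passed among 17 mesenchymal genes, all higher, and BCL2 passed among 14 BCL2 family genes, higher. Lower genes that passed were MERTK and DDR1 (of 16 other receptor tyrosine kinases), DUSP5 (of 15 MAPK output genes), HES1, NOTCH3 and WNT7B (of 14 Wnt and Notch genes), IGFBP3 (of 23 YAP/TAZ targets) and TP63 (of 6 squamous and basal genes). ALDH1A3, CYP24A1 and ABCC3 (of 12 drug transport and metabolism genes) and POU2F3 and SYT1 (of 5 neuroendocrine genes) passed as lower. MUC1 and FOXA1 passed as lower and GATA6 as higher among 6 lung lineage genes, and ITGA6 as lower and BMI1 as higher among 9 stem cell markers. No member of the cell cycle, interferon response, antigen presentation, TGF-beta, immediate early, CDK inhibitor, metabolic, hypoxia, ATF4, ribosomal, cancer-testis or other cell type lists passed in this way.

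The pairs also differed in drug, in sequencing depth and in the transcript set their files list. The test asks for changes common to both pairs, but a low p-value can rest mostly on 1 line. IFI27 had an unadjusted p of 0.00495 in edgeR's quasi-likelihood test, with 10454 and 3460 counts in H1975 and 5 and 3 in HCC827. With 1 residual degree of freedom, simulated 8-fold changes were recovered in 81% of cases and 2-fold changes in 2% at a biological coefficient of variation of 0.4. Simulated changes had the same size in both lines, whereas the observed log2 ratios of the lines had a Pearson correlation of 0.424. These shares therefore do not give how often changes of unlike size in the 2 lines are recovered. All simulated genes also had the same coefficient of variation, so the shares do not give how often real changes are recovered.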

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

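All tests of explanations in this part were chosen after the results were seen. The interferon response list had a median log2 ratio of 0.59 in H1975 and −2.17 in HCC827, a difference (HCC827 minus H1975) of −2.76, and was picked out because the resistant library stood above its sensitive partner in 1 line and below it in the other. The difference was not tested, since each group has 1 library. Scaling of the libraries shifts all genes alike, yet the list stood apart from random lists matched on expression (percentile 100 in H1975, 0 in HCC827). This argues against scaling as its source. The alternative scalings differed too little from the planned one to test it: the HCC827 median was −2.17 with DESeq2 size factors and −2.12 with totals alone. The HCC827 median closest to 0, −1.80, came from log2(FPKM + 1), which is not a rescaling. A candidate explanation is that the resistant HCC827 cells make less type I interferon, because 17 interferon genes lie within a stretch of neighbouring genes near 0 in that library, but these genes had 2 expected counts in all in the sensitive library, too few to decide. The state of the cultures at harvest was not tested and stays open.

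Further genes went in opposite directions in the 2 lines, and for each of them the difference was not tested. OAS2, an interferon-induced gene, differed by −5.38 (HCC827 minus H1975, log2), IGF2, a growth factor gene, by −5.67, the ephrin gene EFNB1 by −3.66, INAVA by −3.73 and CBS, an enzyme of cysteine synthesis, by −2.75. In these 5 genes the resistant library was higher in H1975 and lower in HCC827; IGF2 had 3.03 and 42.2 FPKM in the sensitive and resistant H1975 libraries. The MHC class II gene HLA-DRA differed by 10.10, the lipoprotein gene APOE by 11.72, the monoamine oxidase gene MAOB by 10.80 and AKR1C1 by 7.59, being lower in resistant H1975 and higher in resistant HCC827. APOE had 203 and 2 counts in H1975 (−6.66 [−9.71, −4.79]) and 2 and 70 in HCC827 (5.06 [3.15, 8.13]); HLA-DRA was not listed in resistant H1975, so that its difference rests on a floor, and AKR1C1 and CBS share reads with near-identical genes and are uncertain. On the log2(FPKM + 1) scale IGF2 was under 2-fold in HCC827 (−0.71).

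The epithelial list was lower in both resistant libraries. Scaling of the libraries, which shifts all genes alike, is argued against, since the list stood at percentile 0 among matched random lists in both lines. The alternative scalings differed too little from the planned one to test it: the HCC827 median was −2.31 with DESeq2 size factors and −2.25 with totals alone. Over both lines and 4 alternatives the list median closest to 0, −2.16, was that of HCC827 on log2(FPKM + 1), which is not a rescaling. Fibroblasts in the resistant cultures are argued against by their abundant transcripts: COL1A1 had 9.41 FPKM in resistant H1975, the highest of COL1A1, COL1A2, COL3A1, DCN and LUM in either resistant library, where the gene at abundance rank 100 had 711 FPKM (H1975) or 612 FPKM (HCC827). As a hypothesis, drug resistance itself may go with this change, and 21 list members passed adjusted over the list alone in the test over both lines. With 1 resistant library per line, resistance cannot be told apart from any other difference between the cultures, drug exposure at harvest among them.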

How the results depend on the processing

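Alternatives were planned, except the test over genes listed in at least 1 library of each line, which was added after seeing the data and also called 0 genes. Other scalings (DESeq2 size factors, totals alone), no filter and a pseudocount of 0.1 kept the counts of calls within each line within 1.5 times, as DESeq2 size factors, the only scaling run for them, did for the counts over both lines. Planned counts were 381 higher and 1016 lower in H1975, 838 and 1302 in HCC827, 108 higher and 382 lower in both, and 20 and 65 opposite. Stricter or looser rules moved them by construction. With at least 5 FPKM, 203 genes were higher and 525 lower in H1975, 493 and 841 in HCC827, 55 and 201 in both, and 4 and 23 opposite (higher in H1975 listed before lower). At 1.5-fold the counts were 1105 and 1754, 1816 and 2269, 310 and 707, and 88 and 169. At 4-fold they were 97 and 457, 309 and 458, 19 and 140, and 0 and 14. With the whole interval beyond 2-fold, 243 were higher in H1975 and 525 in HCC827. On log2(FPKM + 1), which shrinks low genes, 202 were higher in H1975, 64 in both, and 5 and 36 opposite. The test over both lines gave 443 genes with DESeq2 and 8 with limma against 0 with edgeR; the cause was not tested. It gave 0 without the block (307 at an unadjusted p under 0.05), with DESeq2 factors and without a filter. With each library left out in turn it gave between 0 and 0, but these fits also dropped the block, since no residual degrees of freedom were left with it, and the lone library of an arm is assumed to vary like the other group. The fit without the block called 0 genes with all libraries too, so these counts say nothing about how stable the blocked result is. Among list medians, 4 changed sign with at least 5 FPKM: squamous and basal in HCC827 (0.68 to −2.55), neuroendocrine in H1975 (−1.17 to 0.41), mesenchymal in H1975 (−0.11 to 0.12) and Wnt and Notch in HCC827 (0.04 to −0.07). Cytosolic ribosomal proteins in HCC827 changed from −0.01 to 0.04 with totals alone and on log2(FPKM + 1). All 365 named ratios kept within their intervals with DESeq2 factors, and 200 moved beyond them on log2(FPKM + 1). On that scale 29 of 272 called named ratios were under 2-fold, among them CRACD in HCC827 (0.99), RBMS3 (0.48 in H1975, 0.80 in HCC827) and, in H1975, AXIN2 (0.69), ROS1 (0.67) and SPRY4 (−0.73). No called ratio changed sign, but the uncalled ratios of PGK1 in H1975 (0.01, close to 0 on each scale) and RPS18 in HCC827 (−0.05 to 0.01) did. The H1975 epithelial median was −2.90 there, so the gap to HCC827 (−2.16) depends on the scale. No paired analysis by replicate number was possible because each group has 1 library.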

Other observations

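All tests and genes in this part were chosen after the results were seen. Neighbouring genes, ordered by the GRCh38.p14 gene table, were lower together in long stretches of the HCC827 resistant library. Around CDKN2A, 13 considered genes in a row from MLLT3 to C9orf72 had 7760 counts in the sensitive and 56 in the resistant library. That was 0.688% (95% interval 0.519 to 0.895%) after scaling. The stretch was extended from CDKN2A while each next gene had a log2 ratio of −3 or below. That rule fixed a low share in advance, and CDKN2A alone held 3759 of the sensitive counts. The interval covers counting error alone, and only 14.3% of the sensitive counts are in genes with whole counts, so read sharing between genes adds an error that it leaves out. They include MTAP, an enzyme of methionine salvage (1113 and 16.7 counts), PLAA (343 and 2, log2 ratio −7.49 [−10.54, −5.63]), MOB3B (275 and 2, −7.17 [−10.22, −5.31]) and FOCAD (553 and 23.4), and 5 of them had no counts, CAAP1 (222 in the sensitive library) and IFT74 (133) among them. Of the 11 that were considered in H1975, none was called there, although MOB3B, below the filter in that line, had 103 counts in the sensitive and none in the resistant library. The next considered gene on the far side, ACO1, had 786 and 877 counts.

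This stretch lay inside a run of 50 genes from PUM3 to ACO1 whose windows of 11 neighbours had medians of −1 or below; 47 of the 50 had a ratio below 0, with a median of −1.78, against 0.02 for the 41 considered in H1975. The run holds RPS6, the only called gene of the fixed list of cytosolic ribosomal proteins, JAK2 (1.41 and 0.40 FPKM), the transcription coactivator gene PSIP1 (1194 and 14 counts) and CD274, which encodes PD-L1 (3.18 and 1.52 FPKM). GLDC and PTPRD in the same run were higher, with log2 ratios of 2.93 and 1.85. Another 4 runs, in a region of the reference separate from the PUM3 to ACO1 run, followed each other. They were PJA1 to RPS4X (20 genes, median −1.20), CHIC1 to TCEAL3 (47 genes, −1.43), NXT2 to HPRT1 (50 genes, −1.07) and INTS6L to EOLA2 (18 genes, −1.14). They hold PGK1, the glycolysis gene with the lowest ratio, DIAPH2 (266 counts and none), PBDC1 (74 and 1, −6.28 [−11.60, −3.76]) and MBNL3 (495 and 20). Against the trend, the CHIC1, NXT2 and INTS6L runs held 2, 2 and 1 genes called higher, among them MAGEC2 (5 and 200 counts) and GPC4 (1 and 50, 5.58 [3.03, 10.91]). In H1975 the longest run had 13 genes, from S100A10 to S100A3, a cluster of epidermal genes.

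Chance order of lower genes is argued against, since the longest run in 1000 shuffled gene orders of HCC827 had 11 genes. Different transcript models are argued against as well, because all 14328 genes listed in both HCC827 files had identical transcript lists. The 176 genes of the long runs listed in both files are part of these and are no separate check. A candidate explanation is that the resistant cells have fewer copies of the DNA in some or all of these separate runs, but RNA alone cannot decide. The genes called higher inside the runs (GLDC, PTPRD, GPC4 and MAGEC2 among them) go against a complete loss of the runs. They do not decide whether some copies were lost, and none of those named lies in the stretch around CDKN2A. The 6 other genes inside the stretch around CDKN2A, which were below the filter, kept 19.86 of 32.2 expected counts, and HACD4 (16.2 and 12.4) made up most of them; their counts are few and partly shared with other genes, so copy loss and silencing of the stretch cannot be told apart here.

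Genes that neighbour EGFR in the reference stood higher in HCC827 than in H1975, as EGFR did. SEC61G had 1256 and 706 FPKM, VOPP1 691 and 550 FPKM and LANCL2 91.3 and 78.9 FPKM in sensitive and resistant HCC827, against 192, 75.8 and 8.76 FPKM in sensitive H1975. IFNB1 had 1 count in sensitive and 16 in resistant H1975, beside the higher interferon list of that library, and was not listed in HCC827.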
